A study of Mus musculus with 3 samples.

How the data were processed

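Ribosome-bound RNA from the dentate gyrus of adult Penk-TRAP mice was sequenced in 3 libraries, which the labels put in 1 group with replicate numbers 1 to 3. Per the labels' protocols, the tissue was homogenised, tagged polysomes were purified with antibodies against the fluorescent tag on magnetic beads, and RNA was extracted from the purified material. Each deposited file holds whole-number read counts per gene symbol for 1 library, followed by summary rows of the counter. The submitters' processing notes name STAR 2.0.0e, HTSeq and the mm10 genome; the annotation, the strand setting and any filter were not given in the sources used here. The deposited counts were not normalised, and replicates were not pooled.

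Summary rows were left out of library sizes and tests. Of all reads listed, 16.3, 38.2 and 21.1% fell on genes in replicates 1 to 3. The share listed without a gene feature was 50.7, 35.4 and 40.5%, the share aligned to several places 32.2, 24.8 and 37.5%, and the ambiguous share 0.763, 1.60 and 0.873%. Genes with near-identical copies, such as ribosomal protein and globin genes, lose reads to the several-places class, so their levels are uncertain. Gene totals were 5348761, 19195559 and 11059982 counts. A gene at 0 counts may be present at up to 3 counts, or 0.707, 0.131 and 0.257 CPM, which covers counting error only, since PCR copies are not independent molecules. Genes with at least 10 counts numbered 8795, 14252 and 12019, a gap that remained in part at equal depth.

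From the counts, log2 CPM with a prior count of 2 and TMM scaling (factors 0.793, 1.19 and 1.06) were computed with edgeR 4.0.16 in R 4.3.3. The filter filterByExpr with 1 group kept 8510 of 32531 genes; it asks in effect for expression in all 3 libraries and so drops genes lost in replicate 1. Levels of single genes were tested with limma 3.58.1 (trend, TREAT with a log2 threshold of 1) on log2 CPM minus the library's median tested gene, with Benjamini-Hochberg adjustment and a threshold of 0.05. Marker lists were compared through the median log2 CPM of all members with a row, unfiltered, per library: cell type lists against the granule cell list, functional lists against the median tested gene. Those differences and 5 preset gene differences were tested with limma, intercept only, each family adjusted by itself. Poisson chi-square tests compared counts with the shares of the effective library sizes. The range of each list between libraries was set against 10000 random lists matched on level in 10 bins. Levels were not corrected for gene length, and across genes they rose with exon length (Spearman 0.329, 0.293 and 0.396 in replicates 1 to 3).

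Design, lists, named genes and most alternatives were set before the data were examined. Named were all opioid genes, the 3 highest and the 1 lowest member of every other list, the 10 tested genes with the highest mean CPM outside ribosomal protein and mitochondrial-encoded genes, and the 10 with the largest range among genes that varied beyond sampling noise at a mean of at least 10 CPM. Some genes this rule names are not reported here. Listed symbols that matched no row, such as Nectin3 and Scn2a, and the mitochondrial-encoded list were not used here. Coordinates, exon lengths and gene classes come from GENCODE vM21 on GRCm38, which may not be the annotation behind the counts; 93.1% of tested symbols matched.

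Alternatives were DESeq2 1.42.0 size factors, no filter, a prior count of 0.5, log2 CPM per kb of exon, ribosomal protein and mitochondrial-encoded genes left out of the library size, other count minimums, means in place of medians, a pan-neuronal reference, no shared members, and each replicate left out. Setting counts below 3 to 3 and thinning all libraries to the total of replicate 1 were added after seeing the data. On simulated counts for 8510 genes, the level test recovered 91.5% of genes set 16-fold above the median gene. Genes set at the median itself gave 0% false calls, a result that the log2 threshold of 1 nearly fixed in advance. The sampling noise test recovered 100% of 4-fold changes with 0.0843% false calls. The list test recovered 100% of lists shifted 8-fold with 6.5% false calls among unshifted lists, which share 1 reference list. The simulated lists were of equal size, at like levels and of independently varying genes, unlike the real lists, so these rates need not hold for them. Figures were drawn with matplotlib 3.10.9.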

Results

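RNA bound to tagged ribosomes was sequenced from the dentate gyrus of adult mice of the Penk-TRAP line NIDA186, on the C57BL/6J strain. In translating ribosome affinity purification (TRAP), a green fluorescent protein fused to the ribosomal protein Rpl10a is made in chosen cells, here under the regulatory DNA of Penk, the proenkephalin gene. Ribosomes carrying the tag are then pulled down with an antibody against the fluorescent protein. All 3 libraries were immunopurified samples of 1 group without treatment, named replicates 1 to 3. They held 5348761, 19195559 and 11059982 counts on genes, in that order. No unbound or whole-tissue library was used here, so levels were compared between genes within a library, and no enrichment over tissue could be computed. Nothing in the labels says whether the replicates came from separate animals, so the spread between them may be technical in part. Each limma p-value rests on that spread as limma shares it across genes, lists or preset differences, not on that of 1 comparison alone.

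Penk, whose regulatory DNA drives the tag, was examined first, with the other opioid genes. Without a whole-tissue library, these levels cannot test whether Penk cells were selected. Penk (chromosome 4, 4133531 to 4138819, minus strand) was present at 13.7, 66.0 and 12.1 CPM (counts scaled to a common library total) in replicates 1 to 3, a mean of 30.6 ± 30.6 (SD, n = 3) from 58, 1511 and 142 counts. This placed it near the median tested gene, at a log2 difference of -0.45 (SE 0.78, adjusted p = 0.956), so that its level could not be told from that gene. The sign turned to 0.52 without replicate 1, 0.18 without replicate 3, 1.18 per kb of exon and 2.30 with no filter. Penk exceeded the other opioid precursor genes in all 3 libraries. Prodynorphin (Pdyn) had 8, 179 and 0 counts, pro-opiomelanocortin (Pomc) 0, 22 and 0, and prepronociceptin (Pnoc) 0, 4 and 0. On the log2 scale Penk was higher than Pdyn by 4.04 (SD 1.97, n = 3, adjusted p = 2.7e-04, limma), with 2.76, 3.05 and 6.32 in replicates 1 to 3. It was higher than Pomc by 6.23 (SD 0.31) and than Pnoc by 6.82 (SD 0.73, adjusted p = 2.9e-07 each, limma). Since several of these counts were 0, the differences depend on the prior count; with counts below 3 set to 3 they were 3.57, 4.93 and 5.52. The call against Pdyn ended without replicate 2 (4.17, adjusted p = 0.109) and with a prior count of 0.5 (4.74, adjusted p = 0.0588).

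The opioid receptor genes differed between the libraries. The delta receptor gene Oprd1 had 10, 91 and 689 counts, and the kappa receptor gene Oprk1 had 123, 36 and 0. The mu receptor gene Oprm1 had 1, 60 and 61 counts, and the nociceptin receptor gene Oprl1 had 0, 245 and 245. These counts are not scaled to library size, so equal counts in replicates 2 and 3 stand for a higher level in replicate 3. A count of 0 allowed up to 0.707, 0.131 and 0.257 CPM in replicates 1 to 3. As a list, the 8 opioid peptide and receptor genes lay below the median tested gene by a log2 difference of -4.45 (SD 1.04, n = 3, adjusted p = 0.00571, limma), lower in 3 of 3 libraries, and by -4.02 with counts below 3 set to 3. Of the 2 members that could be tested singly, 0 differed from the median gene, also when adjusted over the list alone. With no filter on low counts, which lowers the median gene, the list lay at -1.71 and its call ended (adjusted p = 0.0622).

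Rpl10a, whose coding sequence the transgene carries, reached 97.8 ± 26.6 CPM (SD, n = 3) and exceeded the median of the other large ribosomal subunit genes by 1.29 on the log2 scale, higher in 3 of 3 libraries (adjusted p = 0.0260, limma). The call ended without replicate 1 (1.16, adjusted p = 0.347) and with counts below 3 set to 3 (adjusted p = 0.104 at the same difference). Slc17a7, the vesicular glutamate transporter of cortical and hippocampal excitatory neurons, had 207 ± 99.9 CPM, against 67.0 ± 28.4 for Gad1 and 130 ± 63.0 for Gad2, which make GABA. Against the mean log2 level of Gad1 and Gad2 the difference was 1.15 (adjusted p = 0.0456), above 0 in 3 of 3 libraries but only 0.20 in replicate 3. There Slc17a7, at 127 CPM, lay below Gad2 alone, at 197 CPM. Its call ended without replicate 1 (0.94, adjusted p = 0.368), without replicate 2 (0.88, adjusted p = 0.263) and with DESeq2 size factors (1.15, adjusted p = 0.0602).

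**Figure D1:**
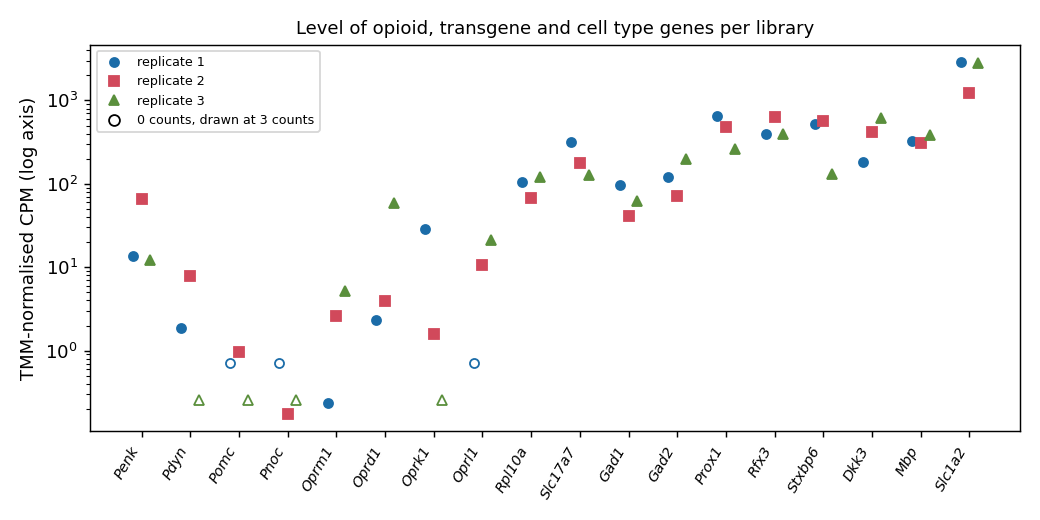
Level of opioid genes, Rpl10a, transmitter genes and cell type markers in each library, as TMM-normalised CPM on a log axis, with 1 symbol per replicate and open symbols for 0 counts drawn at 3 counts. Penk lies at 13.7, 66.0 and 12.1 CPM, above Pdyn, Pomc and Pnoc in each library; the lowest filled symbols stand for 1 count of Oprm1 and 4 counts of Pnoc.

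Levels of cell type markers in the purified RNA were read with marker lists fixed before the data were examined. Without unbound or whole-tissue libraries, RNA carried over in the purification cannot be told from RNA of tagged ribosomes. These levels therefore do not show which cells carried the tag. Markers of dentate granule cells were uneven, and as a list they could not be told from the median gene (0.42 on the log2 scale, adjusted p = 0.616, limma). Rfx3 reached 473 ± 135 CPM, Prox1, the transcription factor of granule cell identity, 464 ± 199, and Stxbp6 409 ± 241 (SD, n = 3). These 3 of 9 tested granule cell markers lay above the median gene, with levels of 3.92, 3.83 and 3.48 on the log2 scale (adjusted p = 5.0e-06, 1.2e-05 and 1.3e-04), and the count adjusted over the list alone was also 3. Without replicate 1, 5 of 12 tested markers lay above. Plk5, the lowest member, had 46, 119 and 3 counts. Other members were at or near 0 in replicate 1: C1ql3 had 0, 1658 and 453 counts, Calb1 2, 1350 and 121, and Tdo2 1, 315 and 114. These 3 genes were chosen after their values were seen. Against the granule cell list, the pan-neuronal list was higher by 3.95 and the glutamatergic list by 2.07 on the log2 scale (adjusted p = 3.0e-06 and 0.00748), both in 3 of 3 libraries. Snap25 led the pan-neuronal list with 7175 ± 3201 CPM, and Camk2a, a kinase of excitatory synapses, led the glutamatergic list with 9853 ± 4132. Above the median gene were 9 of 11 pan-neuronal and 3 of 8 glutamatergic members, or 9 and 4 when adjusted over the list alone. Without replicate 1 the glutamatergic call ended (1.59, adjusted p = 0.0795), with 7 of 8 members above the median gene, as it did without replicate 3 (2.22, adjusted p = 0.0796). On the scale per kb of exon, 6 of 8 members lay above.

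Of 19 lists set against the granule cell list, 15 were lower. The lowest were Cajal-Retzius cells at -7.40, mossy cells at -6.75, microglia at -6.71 and choroid plexus and ependyma at -6.59. In these 4 lists the typical member had counts at or near 0, so the size depends on the prior count; with counts below 3 set to 3 the differences were -6.11, -5.45, -5.88 and -5.50. Single members had counts all the same: the Cajal-Retzius marker Reln, which also stands in the interneuron subclass list, had 71, 1283 and 1509. The mossy cell marker Ajap1 had 189, 973 and 247 counts, and the microglial receptor gene Csf1r 14, 62 and 39. Csf1r, the 1 tested microglial member, lay below the median gene, a call that ended without replicate 1, without replicate 3 and with no filter. Red blood cell genes lay at -5.79, CA2 pyramidal markers at -5.32, stem and cycling cell markers at -3.69 and oligodendrocyte precursor markers at -3.30. Those 8 lists stayed lower whichever replicate was left out, with differences between -7.56 and -2.89. The red blood cell list lay at -2.66 per kb of exon, and with means over members the Cajal-Retzius list lay at -4.89. Of 5 listed red blood cell genes only 3 had a row, globin genes among them. Globin genes lose reads to the several-places class, so the low level of that list is uncertain.

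The other 7 lower lists each lost their call without at least 1 replicate. Immature granule cell markers lay at -3.49, at -2.11 without replicate 1 (adjusted p = 0.0239) and at -4.01 without replicate 3 (adjusted p = 0.0942). Interneuron subclass markers lay at -1.96, and at -1.57 without replicate 1 (adjusted p = 0.0795). GABAergic markers lay at -1.86, and at -1.43 without replicate 2 and -1.55 without replicate 3 (adjusted p = 0.0952 and 0.175). Endothelial and mural markers lay at -1.89, and at -1.37 without replicate 1 and -1.99 without replicate 3 (adjusted p = 0.121 and 0.0942). The thalamic list lay at -1.67, and at -1.33 without replicate 1 and -1.50 without replicate 2 (adjusted p = 0.124 and 0.0865). CA1 markers at -1.48 and CA3 markers at -1.42 lost the call without any single replicate, with differences from -1.98 to -0.87 for CA1 and from -1.79 to -0.78 for CA3. With a prior count of 0.5 the GABAergic, thalamic, CA1 and CA3 calls ended too (adjusted p from 0.0513 to 0.106). The calls of the endothelial and mural, CA1 and CA3 lists ended per kb of exon, at -1.42, -1.43 and -0.54 (adjusted p from 0.0855 to 0.515). Without members shared between lists the CA1 and CA3 calls ended at adjusted p of 0.0510 and 0.0546. The CA3 call also ended with DESeq2 size factors (0.0520), with no filter (0.0517) and with means over members (-1.02, adjusted p = 0.108). Within the CA3 list Dkk3 stood at 404 ± 215 CPM, above the median gene (level 3.56, adjusted p = 4.5e-05).

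Glial genes did not all lie low. The astrocyte list differed from the granule cell list by -1.39 (adjusted p = 0.0501) and the oligodendrocyte list by -0.79 (adjusted p = 0.254), neither past the threshold; replicate 3 lay at -0.12 and 0.47. The astrocyte difference passed with counts below 3 set to 3 (-1.39, adjusted p = 0.0209) and with libraries thinned to replicate 1 (-1.39, adjusted p = 0.0218), both settings added after seeing the data. Per kb of exon it was -0.64 (adjusted p = 0.462), and the oligodendrocyte sign turned (0.17, adjusted p = 0.825). Against the pan-neuronal list, itself higher than granule cells, both lists were lower in 3 of 3 libraries, at -5.34 and -4.73 (adjusted p = 1.0e-07 and 1.0e-06). The astrocytic glutamate transporter gene Slc1a2 reached 2299 ± 928 CPM (level 6.13, adjusted p = 3.9e-08). The myelin genes Mbp and Mobp had 338 ± 37.2 and 226 ± 82.5 CPM, with levels of 3.46 and 2.83 (adjusted p = 4.3e-05 and 0.00165). Above the median gene were 1 of 8 tested astrocyte and 3 of 7 tested oligodendrocyte members, the same counts as when adjusted over the list alone. Over all tested genes, 1196 of 8510 lay above it, so the astrocyte count by itself shows no excess. Rgs5, a pericyte gene, reached 395 ± 341 CPM (level 3.12, adjusted p = 0.00201; without replicate 2, 2.31, adjusted p = 0.130). The standard error of every list difference against granule cells was 0.68, since limma pooled the spread over the lists. The SD between libraries ran from 0.19 for red blood cell genes to 2.42 for immature granule cell markers. These p-values therefore do not reflect the spread of each list by itself. All 19 comparisons share the granule cell values, and the exact sign-flip test of 3 libraries cannot give a p below 0.25.

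**Figure D2:**
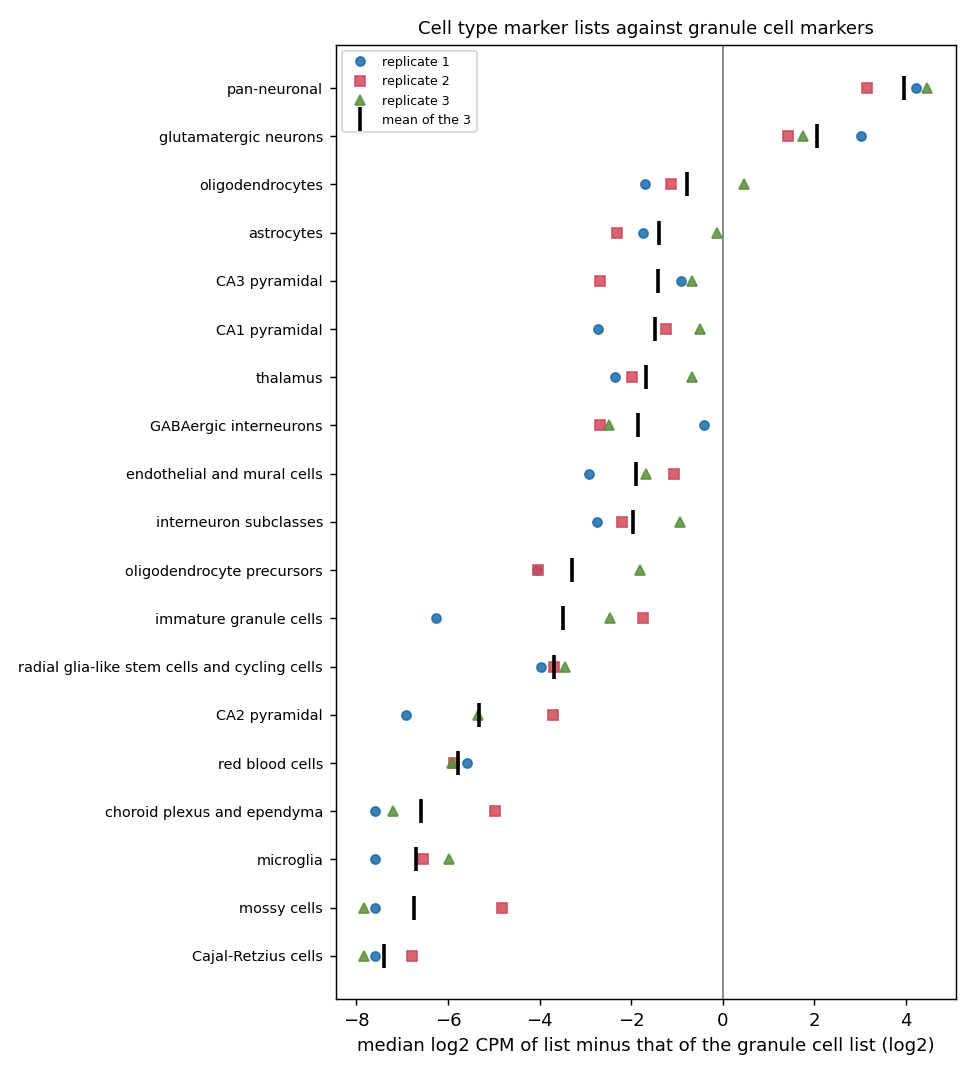
Median log2 CPM of each cell type marker list minus that of the granule cell list, with 1 symbol per replicate and a bar at the mean of the 3. The pan-neuronal and glutamatergic lists lie to the right of 0 at 3.95 and 2.07, and the Cajal-Retzius list lies farthest to the left at -7.40.

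Of the 3 functional lists above the median gene, 2 hold ion channel and receptor genes. Voltage-gated channel genes lay above the median gene by 1.84 on the log2 scale (SD 0.11, n = 3, adjusted p = 0.00571) and GABA receptor genes by 1.81 (SD 0.18, adjusted p = 0.00571), both in 3 of 3 libraries. Among channels, the sodium channel gene Scn8a reached 2403 ± 1011 CPM and the calcium channel gene Cacna1e 1341 ± 314, and 12 of 25 tested members lay above the median gene (13 adjusted over the list alone). The channel list lay at 1.08 per kb of exon (adjusted p = 0.0240), with 6 of 25 members above. Hcn4 had 0 counts in each library. Of the GABA receptor genes, 7 of 12 tested lay above, among them Gabrb2 at 385 ± 60.1 CPM and Gabbr1 at 338 ± 68.3, and the count was also 7 adjusted over the list alone; with means over members that list lay at 1.03 (adjusted p = 0.0286). Gabrd, the delta subunit gene of extrasynaptic receptors, had 0, 27 and 0 counts. Ionotropic glutamate receptor genes lay at 1.42 and missed the threshold (adjusted p = 0.0835), although 6 of 12 tested members lay above, Gria2 at 1533 ± 397 and Gria3 at 1096 ± 250 CPM among them. That list passed without replicate 1 (1.62, adjusted p = 0.0403) and with means over members (0.84, adjusted p = 0.0388), but lay at 0.30 per kb of exon (adjusted p = 0.342), with 3 of 12 above. With no filter on low counts, which lowers the median gene, 10 functional lists lay above it and 1 below.

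Without correction for length, nuclear long noncoding RNAs lay highest of the functional lists, at 4.22 above the median gene (SD 0.98, n = 3, adjusted p = 0.00571), with 5 of 9 members above it and 6 adjusted over the list alone. Malat1 (chromosome 19, 5795690 to 5802672, minus strand) made up 6.71, 1.98 and 3.47% of gene counts in replicates 1 to 3, and Meg3 reached 6841, 1388 and 3438 CPM. Xist, which also stands in the sex-linked list, had 1116, 529 and 2110 CPM and was the median member in replicate 1. Per kb of exon the list lay at 1.29 and its call ended (adjusted p = 0.241), below the values of 1.76 for large ribosomal subunit and 1.33 for GABA receptor genes. Monoamine and acetylcholine receptor genes lay below the median gene at -3.30 (adjusted p = 0.0129), with Chrm1, a muscarinic receptor gene, highest at 76.0 ± 27.2 CPM and Drd3 at 0 counts in each library; without replicate 1 the list lay at -1.98 (adjusted p = 0.0199), and with no filter its call ended (-0.56, adjusted p = 0.516). Other neuropeptide genes lay at -7.02 (adjusted p = 0.00397), or at -5.72 with counts below 3 set to 3. Cck at 158 ± 73.6 and Sst at 94.0 ± 27.2 CPM were their highest members, and Trh had 0 counts in each library. Cck was the 1 neuropeptide above the median gene (level 2.24, adjusted p = 0.0382), a call that ended without replicate 2 (adjusted p = 0.289) and without replicate 3 (2.15, adjusted p = 0.204).

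With the ionotropic list, 8 functional lists did not pass the threshold. Peptide processing and granule protein genes lay at 0.43 (adjusted p = 0.256), with Chgb at 387 ± 362 CPM. Immediate early genes lay at -0.89 (adjusted p = 0.148), with 4 of 14 tested members above and 1 below; Egr3 at 275 ± 155, Nr4a2 at 185 ± 97.6 and Egr1 at 182 ± 134 CPM were the highest. With means over members that list passed as below the median gene (-1.60, adjusted p = 0.00570), whereas with no filter it passed as above (1.86, adjusted p = 0.0471). Its members above numbered 2 of 13 without replicate 2, 2 of 14 without replicate 3 and 1 of 12 when thinned to replicate 1. They numbered 5 of 16 without replicate 1 and 10 of 20 with no filter, with 3 below in each of these settings. Metabotropic glutamate receptor genes lay at 0.57 (adjusted p = 0.224), led by Grm5 at 301 ± 3.51 CPM, and at -0.36 with means over members. Neurotrophic and stress hormone receptor genes lay at 0.61 (adjusted p = 0.148), led by Ntrk2 at 355 ± 123 and Igf1r at 328 ± 128 CPM, and passed without replicate 1 (1.49, adjusted p = 0.0327); the sign turned per kb of exon (-0.26) and with means over members (-0.19). Oxidative phosphorylation genes lay at -0.37 (adjusted p = 0.565), a sign that turned without replicate 1 (0.99, adjusted p = 0.0845) and per kb of exon (0.59). Large ribosomal subunit genes lay at 0.41 (adjusted p = 0.166), with Rpl4 at 341 ± 101 CPM; per kb of exon they passed (1.76, adjusted p = 0.0104), and with means over members they lay at -0.024. The sex-linked list lay at -3.57 (adjusted p = 0.148).

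**Figure D3:**
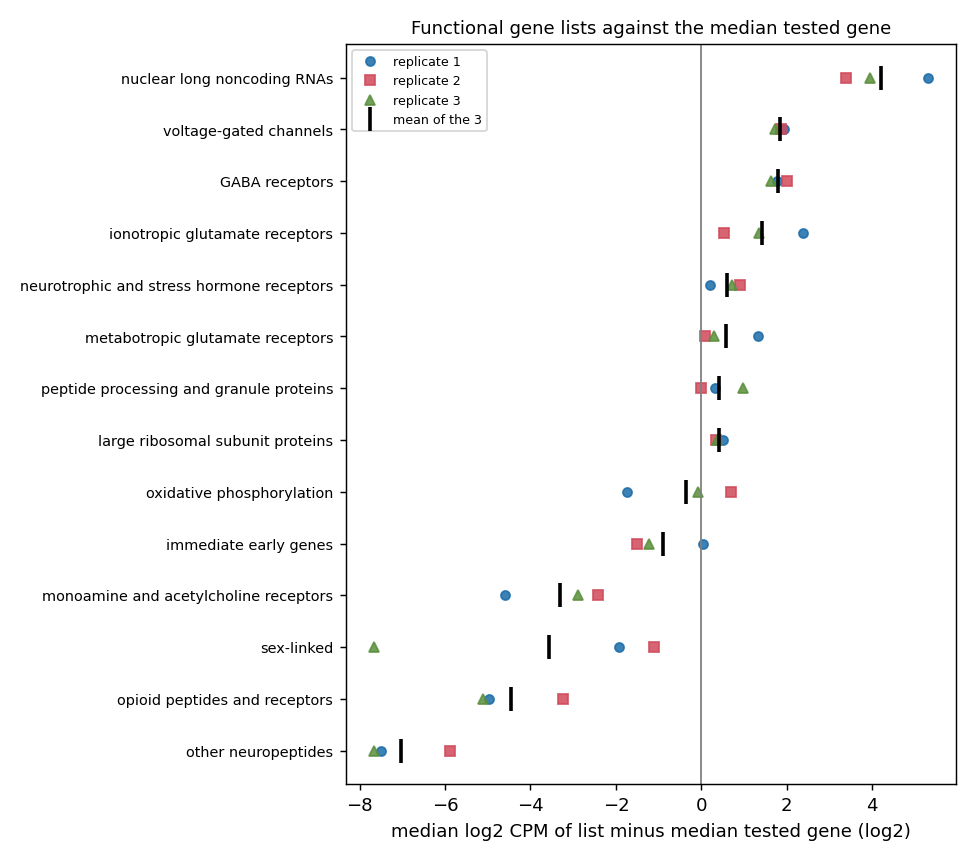
Median log2 CPM of each functional list minus that of the median tested gene, with 1 symbol per replicate and a bar at the mean of the 3. Voltage-gated channels and GABA receptors lie at 1.84 and 1.81 with the 3 replicates close together, whereas other neuropeptides lie at -7.02.

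Across all genes, 8510 were tested, 7905 had at least 10 counts in each library, and 1196 lay above and 444 below the median gene by more than a log2 difference of 1 (limma TREAT). The member counts given for the lists are to be read against that share of all tested genes. The highest mean levels outside ribosomal protein genes belonged to Malat1, the ribosomal RNA precursor Rn45s, AK140265, Cdr1, Camk2a, Map1b, Snap25, Lars2, Ywhaz and Ank2. Map1b, a microtubule protein gene of neurites, had 8398 ± 4212 CPM, Ywhaz 4556 ± 1532 and Ank2 4150 ± 1396 (SD, n = 3). Rn45s took 5.57, 1.59 and 1.05% of gene counts in replicates 1 to 3, Cdr1 2.02, 0.529 and 1.19%, and Lars2 1.19, 0.190 and 0.153%. Since strand was not given, reads counted on these rows cannot be told from reads of overlapping transcripts on the other strand. Without replicate 1 the numbers above and below the median gene were 2173 and 910. There the filter was run anew on the remaining libraries, so these are not counts among the same 8510 genes. Of granule cell markers, for example, 12 were tested in place of 9.

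The replicates were compared gene by gene. Across genes, which are not independent replicates, log2 CPM had Pearson correlations of 0.648 between replicates 1 and 2, 0.622 between 1 and 3, and 0.810 between 2 and 3. The common biological coefficient of variation was 77.1%, and 8286 of 8510 tested genes (97.4%) varied by more than Poisson sampling noise over the 3 libraries. That test covers counting error only and takes PCR copies for independent molecules, so its count does not measure how far separate samples differ. Between pairs, 86.8% of tested genes did so for replicates 1 and 2, 85.9% for 1 and 3, and 86.4% for 2 and 3, so that no pair looked like a repeated deposit. Of the 10 tested genes with the largest range, 9 were highest in replicate 1: A330015K06Rik had 3466, 53 and 105 counts, Ubox5 1459, 56 and 11, Diexf 1246, 417 and 11, and Fam120aos 1196, 175 and 13. AK158583, Prune, Prkd1, N6amt2 and Etfb followed. Copb2, a coat protein gene of Golgi transport, went the other way with 5, 2462 and 2652 counts. The filter on low counts removes genes at or near 0 in 1 library, such as C1ql3, whose log2 range of 8.88 exceeded the 8.37 of A330015K06Rik. With no filter, a setting added here after seeing the data, the 10 genes with the largest range shared 0 with those above, and 10 of 10 were highest in replicate 1. Thinned to the total of replicate 1, also added after, 2 of the genes above stayed among the 10 widest, and 9 of 10 were highest in replicate 1. Strand was not given in the sources used here, so the antisense gene A330015K06Rik cannot be told from overlapping genes.

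Some lists moved between replicates more than random lists of the same size and level. The range of the mean log2 CPM was 1.88 for nuclear long noncoding RNAs (percentile 99.9), 1.72 for oxidative phosphorylation (99.4), 1.87 for endothelial and mural genes (98.2) and 1.45 for granule cell markers (98.1). The noncoding list includes the sex-linked gene Xist. Immediate early genes had a range of 1.14 (97.1), interneuron subclasses 1.60 (96.3) and oligodendrocyte genes 1.44 (95.1). Atp5b, an ATP synthase subunit gene, had 339, 1468 and 1437 CPM and Stxbp6 520, 575 and 132. Pan-neuronal genes had a range of 0.05 (0.83). These percentiles describe these libraries and carry no p-value.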

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

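The tests of lost molecules and of sex-linked genes below were chosen only after the result was seen. The tests of depth, of length and GC, and of other noncoding genes were set before their results were seen, although the list levels of each library were already known. The design has 1 group, so no biological explanation was tested.

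Reads listed without a gene feature made up 50.7% of replicate 1, 35.4% of replicate 2 and 40.5% of replicate 3. They lie outside the counts used for the comparisons.

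Replicate 1 had the fewest genes with at least 10 counts, 8795 against 14252 and 12019. The tables argue against depth alone: thinned to its total over 20 draws, replicates 2 and 3 still had 1.40 and 1.25 times as many. Loss of molecules before amplification may contribute. At equal depth, 8 of 2805 genes with at least 50 CPM in both other libraries had 0 counts in replicate 1, against 0 in replicates 2 and 3. This rests on few genes; at full depth, 135 of 2575 such genes lay more than 10-fold below the mean of the others in replicate 1, 10 of 2251 in replicate 2 and 25 of 2265 in replicate 3.

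Nuclear long noncoding RNAs were higher in replicate 1 by a median log2 difference of 1.65, with 5 of 9 members above both other libraries. After a fit on transcript length and GC content the median was 1.45 (95% bootstrap interval -0.01 to 2.65), too wide for 9 genes to decide. More nuclear RNA in replicate 1 may contribute. The same difference was taken for 127 other noncoding genes after a fit on length, GC content and mean level. Its median lay 0.91 above that of protein-coding genes on the log2 scale (95% bootstrap interval 0.55 to 1.46). Both intervals resample genes, so they do not measure the spread between libraries. A different cell makeup was not tested and stays open.

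Y-linked genes had 524, 1434 and 0 counts in replicates 1 to 3, and Xist had 4735, 12119 and 24659. The tables argue against depth as the reason for the 0, since 826 Y-linked counts were expected in replicate 3 at the lower share of the others. The same value argues against all 3 libraries being repeats of 1 tissue sample; whether replicates 1 and 2 are stays open. Reads of the X-linked homologs counted on Y-linked genes are also unlikely, since replicate 3 had 4930 homolog counts and 0 on the Y. Y-linked and Xist counts together in replicates 1 and 2 may come from tissue of both sexes pooled in 1 library; the labels give no sex, and this was not tested.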

How the results depend on the processing

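No paired analysis was possible because the samples form 1 group. Setting counts below 3 to 3 and thinning to the total of replicate 1 were chosen after seeing the data, as were the synaptic and opioid partner genes. DESeq2 scaling moved the median tested gene by 0.08, -0.06 and -0.02 in replicates 1 to 3, and total counts alone by -0.33, 0.25 and 0.08. Depth limits low genes most in replicate 1. Leaving ribosomal protein genes out of the library size changed no call, which it could hardly do, since levels were compared within each library. The signs of Penk above Pdyn, Pomc and Pnoc held in every setting run.

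With no filter the median gene falls, since many near-empty genes enter: 4252 genes lay above and 4078 below it, 10 functional lists above and 1 below, and 15262 genes varied beyond sampling noise. Per kb of exon, 775 genes lay above. Leaving out 1 replicate gave 939 to 2173 genes above and 363 to 910 below the median gene, 3 to 5 functional lists above it, and 10 to 11 cell type lists below granule cells. The filter was run anew each time, so the tested genes differed. Slc17a7 against Gad1 and Gad2 missed the threshold with DESeq2 size factors (1.15), no filter (1.15), a prior count of 0.5 (1.15), counts below 3 set to 3 (1.15) and thinning (1.08), at adjusted p from 0.0530 to 0.118, and ranged from 0.88 to 1.62 with 1 replicate left out. Where the difference itself stayed the same, the call moved because limma pools the spread over the 5 preset differences. That holds for Rpl10a with counts below 3 set to 3 (1.29); it ranged from 1.15 to 1.56 with 1 replicate left out. Penk minus Pdyn was 4.74 with a prior count of 0.5, past the threshold no longer, and ranged from 2.91 to 4.89 with 1 replicate left out.

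Of the 41 genes whose sign against the median gene turned in any setting, 0 had passed the threshold in the main test, and of 7 lists, 1. With no filter, the sign turned for Grik4 1.97, Top2a 1.07, Nes 0.56, Cspg4 0.82, Pdgfra 0.46, Gpr17 0.15, Kcnj13 1.06, Kl 1.05, Ebf3 0.65, Lhx9 1.90, Slc17a6 1.73, Tubb3 0.97, Penk 2.30, Oprd1 0.90, Grp 0.23, Chrnb2 2.69, Htr1a 2.11, Mirg 1.21, A330015K06Rik 2.54, Ubox5 1.13, Diexf 1.99, Fam120aos 1.63, AK158583 1.12, Prkd1 1.38, N6amt2 1.67, Etfb 1.36, Dlgap3 2.24, Ppfia3 1.86, Adcy8 0.54, immediate early genes 1.86, oxidative phosphorylation 2.38. Per kb of exon length, the sign turned for Elavl2 -0.61, Mki67 -0.59, Flt1 -0.21, Kcnj13 0.31, Reln -1.53, Rora -0.17, Satb1 -0.54, Penk 1.18, Fam120aos 0.39, Copb2 -0.27, Etfb 0.73, Dlg1 -0.67, Unc13b -1.14, oligodendrocytes 0.17, neurotrophic and stress hormone receptors -0.26, oxidative phosphorylation 0.59. Thinned to replicate 1, the sign turned for Elavl2 -0.17, Ajap1 -0.053, Mpped1 -0.22, Mki67 -0.018, Prune -0.26. With means over members, the sign turned for metabotropic glutamate receptors -0.36, neurotrophic and stress hormone receptors -0.19, large ribosomal subunit proteins -0.024. Against the pan-neuronal list, the sign turned for glutamatergic neurons -1.88. Leaving out 1 replicate turned the sign for A330015K06Rik (range -2.08 to 1.44), Ajap1 (range -0.045 to 0.71), Chrnb2 (range -0.078 to 0.70), Copb2 (range -1.15 to 2.98), Diexf (range -2.17 to 1.46), Elavl2 (range -0.14 to 1.13), Etfb (range -2.81 to 0.21), Fam120aos (range -2.69 to 0.82), Htr1a (range -1.07 to 0.065), Lhx9 (range -1.31 to 0.64), N6amt2 (range -2.14 to 0.98), Penk (range -1.28 to 0.52), Ppfia3 (range -1.52 to 0.65), Prkd1 (range -2.72 to 0.50), Prune (range -1.50 to 1.83), Ubox5 (range -3.59 to 0.17), oxidative phosphorylation (range -0.99 to 0.99). Except with no filter, where the lower reference turns them, and against the pan-neuronal list, whose level is itself higher, the cause was not tested.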

Other observations

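The lists here were written after the data were seen and are not independent evidence: Shank1, Kalrn, Ppp1r9a, Pclo and Vamp2 had been seen among the most abundant genes before the synaptic lists were drawn up. Counts without those 5 genes are therefore given beside the full ones.

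Of the postsynaptic density genes, 11 of 16 tested members lay above the median gene (limma TREAT), or 8 of 13 without the genes seen beforehand. Dlg2, a scaffold of glutamate receptors, had 1299 ± 297 CPM (SD, n = 3; level 5.38) and Dlgap1 1251 ± 103 (level 5.35). Of the presynaptic active zone genes, 9 of 13 lay above, or 7 of 11 without the genes seen beforehand, among them Bsn at 1567 ± 970 and Ppfia2 at 538 ± 117 CPM. Many of these genes are long. Per kb of exon the postsynaptic counts were 7 of 16 and 4 of 13, and the presynaptic counts 6 of 13 and 4 of 11.

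Of 14 listed partners of opioid receptors, none seen beforehand, 11 could be tested and 8 lay above the median gene; 5 did so without replicate 2 and 6 per kb of exon. The G protein gene Gnao1 reached 1334 ± 99.5 CPM (level 5.45) and the adenylyl cyclase gene Adcy1 1336 ± 746 (level 5.31). The potassium channel genes Kcnj3 and Kcnj6 reached 166 ± 53.8 and 204 ± 23.1 CPM. Without replicate 2, Gnai1 (2.47, adjusted p = 0.0748), Kcnj3 (2.08, adjusted p = 0.238) and Rgs7 (1.94, adjusted p = 0.322) lost their calls. Rgs7 also lost it without replicate 3 (2.61, adjusted p = 0.0542). Per kb of exon, Kcnj6 (2.14, adjusted p = 0.0770) and Rgs7 (2.10, adjusted p = 0.0989) lost theirs. Thinned to replicate 1, Kcnj3 (2.09, adjusted p = 0.0563) and Rgs7 (2.01, adjusted p = 0.0827, limma TREAT) did so. Gnai2, Gnaz and Adcy8 did not pass the threshold, and Gnai3, Gnb2 and Kcnj9 could not be tested, with Gnb2 at 0, 1.75 and 0.342 CPM. These genes were not tested against the receptor genes, and they serve many receptors, so their level does not single out opioid signalling.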
